A study of Mus musculus with 2 samples.

How the data were processed

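Single-nucleus RNA sequencing was carried out on the cortex of male mice, with nuclei barcoded 7 days after injury. The injury was midline fluid percussion, a diffuse brain injury, and on each diet 1 group had it and 1 group did not. Mice were kept on a vehicle diet or on a diet with PLX5622, which blocks the receptor CSF1R that microglia need to survive. Both libraries, numbered 6142 and 6562, held nuclei of all 4 treatment groups mixed together. Per the labels' protocols, nuclei were extracted and libraries prepared with Parse Biosciences kits of the first version. In this split-pool method fixed nuclei receive a barcode in each of several rounds of wells, and the well of the first round records which suspension a nucleus came from.

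The values the authors deposited are raw transcript counts, which are unique molecular identifiers per barcode and gene column, per the file headers. The deposited cell metadata give counts of genes, transcripts and reads for each barcode, the wells, and 1 of 4 condition codes. A further deposited column of scaled transcript counts was the transcript count times 1.61 in library 6142 and 2.84 in library 6562, and it was not used. The genome build mm39 and Seurat 4.1.1 are named in the submitters' processing notes. The aligner and the counting program are not given in the sources used here. The sum of the matrix over each barcode equalled the transcript count of the metadata in 100% of barcodes of both libraries. Barcodes were listed from 10 transcripts upwards, so background barcodes, which hold free RNA and no nucleus, had not been taken out.

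Each condition code covered 1 row of 12 first-round wells, 48 wells in all. No source used here ties a code to a treatment or a well to a mouse, and none pairs the 56748 gene columns with gene names. Codes were not assigned to treatments from their values, and columns were not named from their place in an annotation. The 5 comparisons that the design implies were therefore not made, and neither were the tests of gene lists or the naming of clusters by markers. Those are the effect of injury on each diet, the effect of PLX5622 with and without injury, and their interaction. The values of each code are given instead, with no p-value between codes and no count of changed genes. Ratios between codes appear only in the closing section, as descriptions of these libraries. Those of reads per transcript, median transcripts and barcode counts are given without a bound. Nuclei and barcodes were not treated as replicates. Shares carry exact Clopper-Pearson 95% intervals and counts exact Poisson 95% intervals, which cover counting error only. For a count of 0 the limit stated is 3 counts of the total.

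A barcode passed with at least 500 transcripts and 300 genes, a rule set before the data were examined. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable columns and 30 principal components were taken. Leiden clusters were made at resolution 1 on an exact graph of 15 neighbours. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 and igraph 0.11.9. On simulated data made from the deep barcodes of library 6142, with 5 populations set apart by 200 columns at 6-fold each, the clustering returned the 5 populations with an adjusted Rand index of 1. The simulated populations were of equal size, with no background or doublets, so recovery of a rare or shallow cluster was not tested. Doublets were sought per library with scrublet among barcodes of at least 3000 transcripts. It marked 3 of 8762 barcodes in library 6142 and 1 of 24998 in library 6562. These shares, 0.034% and 0.004%, lie below the 0.5% under which the caller was taken to have failed, so no barcode was removed and doublets remain in every value.

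The planned rule admitted many background barcodes, and several choices were made after seeing the data. A set of deep barcodes, with at least 3000 transcripts and 300 genes, was taken near the trough between the modes of codes 1 and 2. Clusters of the passing barcodes were called deep where their median reached 1600 transcripts. Clusters were also made anew at minimums of 1000, 2000, 3000 and 5000 transcripts, of which 1000 was planned. Cluster 24 of the deep set was followed because, among clusters of at least 200 barcodes, its share in code 2 had the largest ratio to that in code 1. Other clusters differed by more percentage points. Its 10 marker columns were the columns of at least 50 transcripts in the cluster with the largest ratio to the other deep barcodes in code 2 of library 6142. Their level is given as CPM, computed here over all transcripts of a code. The remaining settings tried, fixed beforehand, were another resolution, a mean for the median, and each library alone.

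Relations across the 12 wells of a code were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 8 relations. Wells are not known to be separate animals, so these p-values describe wells. The codes were also compared between libraries by a chi-square test over columns, which gave 3.53 to 6.78 per degree of freedom. That is more than the counting noise of single transcripts, but transcripts come grouped by nucleus, which this test leaves out. Equal barcodes of the libraries were not merged, because 1291 deep barcodes were shared where 1176.38 were expected by chance. The cause of the excess over that expectation was not tested. The libraries were clustered together, with no correction for library.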

Results

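The data came from mouse cortex and addressed how injured cortex responds with and without microglia, the resident immune cells of the brain. Libraries 6142 and 6562 held 190058292 and 418074254 transcripts. They were read with 275908851 and 507395470 reads, or 1.45 and 1.21 reads per transcript. Transcripts fell in 35509 and 40064 of the 56748 gene columns, and the 10 most abundant columns took 9.92% and 10.3% of them. The libraries listed 420238 and 431873 barcodes, 94.997% and 97.628% of the 442368 that the wells allow. Most listed barcodes held little RNA, with medians of 115 and 318 transcripts.

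The 4 condition codes received very unequal amounts of RNA. Over both libraries code 2 held 62.8% of transcripts, code 1 23.5%, code 3 6.93% and code 4 6.75%. The order was the same in each library, with code 2 at 63.2% and 62.6%, code 1 at 23.4% and 23.6%, code 3 at 6.97% and 6.92%, and code 4 at 6.52% and 6.85%. The treatment behind each code is not used here, so none of these values is an effect of injury or of PLX5622.

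At the planned minimum 203744 barcodes passed, 45218 in code 1, 131560 in code 2, 15854 in code 3 and 11112 in code 4. Their median transcripts were 733, 1039, 840 and 780, and their median genes 500, 688, 558 and 521. The order of the codes by median transcripts was not the same in each library: it was 806, 758, 988 and 1024 in library 6142, where code 2 was lowest, and 724, 1150, 804 and 743 in library 6562. At a minimum of 1000 transcripts code 1 was highest, with 3527, 1769, 1517 and 1939. Across the 8 combinations of library and code, passing barcodes ranged from 2195 to 95404 with a median of 10487. Passing barcodes held 75.9%, 93.7%, 43.4% and 37.2% of the transcripts of codes 1 to 4. In library 6562 the median over all listed barcodes of code 2 was 1036 transcripts, so the minimum of 500 lay inside the background of that code.

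Deep barcodes, with at least 3000 transcripts, were far fewer. Code 1 had 7131, code 2 24876, code 3 650 and code 4 1103, with median transcripts of 8935, 7933.5, 3925 and 4295. They held 54.5%, 64.7%, 6.88% and 13.4% of the transcripts of their codes. Codes 1 and 2 had a separate upper mode in both libraries, while codes 3 and 4 had none. In library 6142 the upper mode of code 1 lay between 10000 and 13335 transcripts and that of code 2 between 7499 and 10000.

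**Figure D1:**
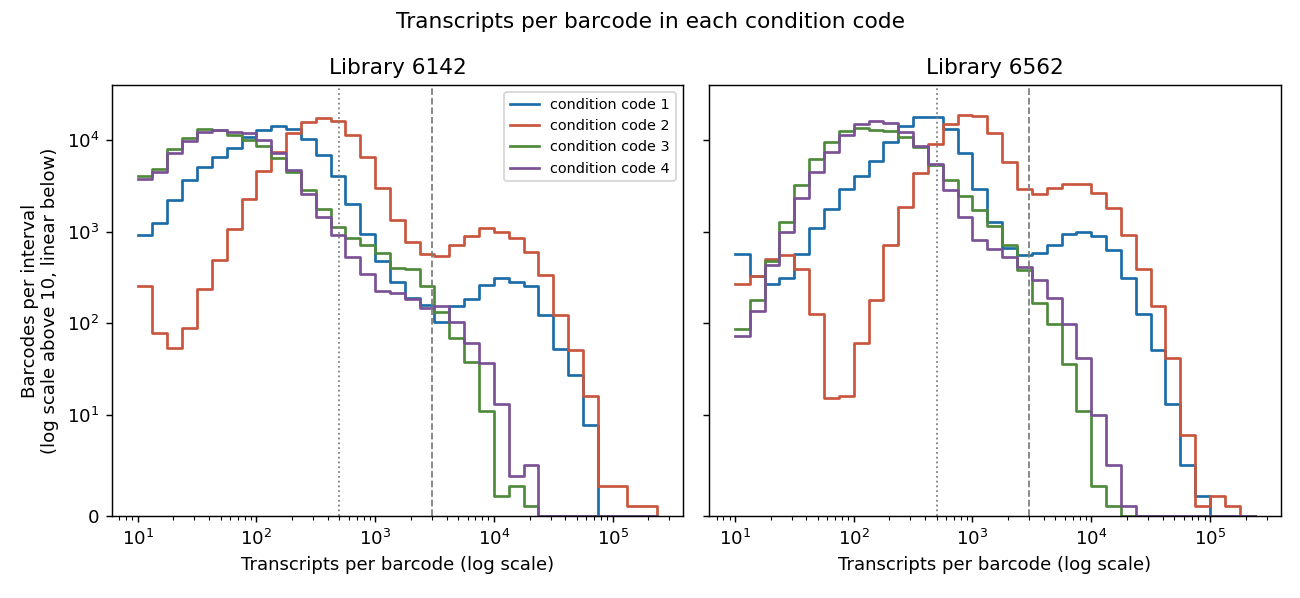
Barcodes per interval of transcripts (vertical axis, log scale above 10 and linear below) against transcripts per barcode (horizontal axis, log scale), with 1 line per condition code and 1 panel per library; the dotted line marks 500 transcripts and the dashed line 3000. Codes 1 and 2 show an upper mode in both libraries, and codes 3 and 4 show none.

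Wells of a code also differed from one another. In library 6562 deep barcodes per well ran from 160 to 546 in code 1, 1099 to 1794 in code 2, 4 to 89 in code 3 and 14 to 173 in code 4. Wells whose barcodes had a higher median of transcripts, a measure of background, held more deep barcodes. Pearson's r over 12 wells was 0.81, 0.89, 0.81 and 0.53 for codes 1 to 4 in library 6142, and 0.83, 0.94, 0.85 and 0.70 in library 6562. Spearman's rho was 0.77, 0.79, 0.65 and 0.52, and 0.80, 0.88, 0.86 and 0.68. The permutation p of r was 0.0019, 0.00019, 0.0026 and 0.073, and 0.00023, 1e-05, 0.00064 and 0.014, of which 1e-05 is the smallest that the permutations can give. For rho the permutation p was 0.0051, 0.0033, 0.025 and 0.085, and 0.0026, 0.00027, 0.00078 and 0.017. After Benjamini-Hochberg adjustment over the 8 relations the permutation p of r ran from 8e-05 to 0.073, and the relation of code 4 in library 6142 missed 0.05. Without the 2 wells farthest from the median count of deep barcodes, r was 0.60, 0.81, 0.54 and 0.41, and 0.81, 0.89, 0.75 and 0.46.

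**Figure D2:**
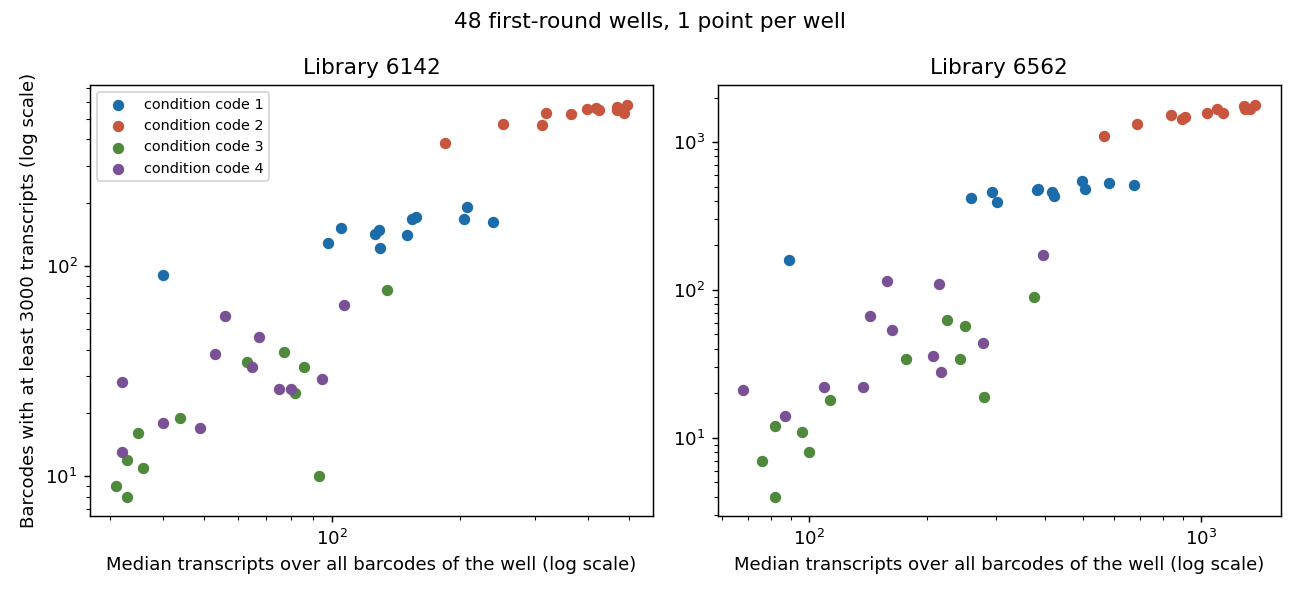
Deep barcodes per first-round well (vertical axis, log scale) against the median transcripts of all barcodes of the well (horizontal axis, log scale), with 1 point per well, colours for condition codes and 1 panel per library. Within each code wells with a higher median tended to hold more deep barcodes, with r from 0.53 to 0.94.

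Clustering of all passing barcodes gave 19 clusters. Of these 5 were shallow, with median transcripts of 645 to 1198, and they held most barcodes. The other 14 had medians of 1826 to 8347.5 transcripts and held 51823 barcodes, or 25.4%. Cluster medians were taken over all codes. The barcodes of codes 1 to 4 in these clusters had median transcripts of 6948.5, 5894, 1273 and 1924. The median of code 3 thus lay below the lowest cluster median. A share in deep clusters is therefore not a share of deep barcodes, which were 650 of the 15854 passing in code 3. In code 1, 20.2% of passing barcodes lay in such deep clusters (95% interval 19.9% to 20.6%). The share was 24.8% in code 2 (24.52% to 24.99%), 40.7% in code 3 (40.0% to 41.5%) and 32.8% in code 4 (31.9% to 33.7%). The order of codes 1 and 2 was reversed in library 6142, where the shares of codes 1 to 4 were 34.6%, 23.8%, 56.9% and 51.9%, against 17.7%, 25.1%, 35.6% and 28.1% in library 6562. It was also reversed at a minimum of 1000 transcripts, with 62.8% in code 1 and 45.1% in code 2. The background was not alike: the median over all listed barcodes in library 6562 was 389, 1036, 154 and 165 transcripts for codes 1 to 4.

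The deep barcodes alone formed 36 clusters of 17 to 3878 barcodes. Of these, 25 clusters occurred in all 4 codes and held 94.2% of deep barcodes, and the 10 largest held 70.8%. The largest, cluster 1, took 11.9% of code 1 (11.1% to 12.7%), 11.1% of code 2 (10.7% to 11.5%), 14.9% of code 3 (12.3% to 17.9%) and 16.2% of code 4 (14.1% to 18.5%). Cluster 12 took 4.50% (4.03% to 5.01%), 2.66% (2.46% to 2.86%), 0.31% (0.037% to 1.11%) and 0.91% (0.44% to 1.66%). Its 2 barcodes in code 3 were both from library 6562. Cluster 16 took 0.49% (0.34% to 0.68%), 1.75% (1.59% to 1.92%), 12.6% (10.2% to 15.4%) and 1.54% (0.90% to 2.46%). Library 6562 gave higher shares of it in every code: 0.54% against 0.34% in code 1, 2.002% against 1.017% in code 2, and 17.98% against 6.12% in code 3. In code 4 it held 17 of 706 barcodes, or 2.41%, in library 6562 and 0 of 397 in library 6142. Across the 36 clusters, shares in the libraries correlated with r of 0.99, 0.99, 0.80 and 0.96 for codes 1 to 4. Clusters are not independent replicates, and cluster numbers carry no cell type, since the columns that define them are not named here.

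Cluster 24, with 305 barcodes and a median of 5073 transcripts, was nearly missing from some codes. It held 3 of 7131 deep barcodes in code 1, or 0.042% (0.0087% to 0.12%). These were 2 of 1781 in library 6142, or 0.112%, and 1 of 5350 in library 6562, or 0.019%. In code 2 it held 297 of 24876, or 1.19% (1.06% to 1.34%), and in code 3 5 of 650, or 0.77% (0.25% to 1.79%). Code 4 had 0 of 1103, which allows a share of up to 0.272%. The shares depended on the minimum. Among deep-cluster barcodes, the cluster matched to it held 1.23%, 6.22%, 2.77% and 1.46% of codes 1 to 4 at 500 transcripts, where it also took in other barcodes, and 0.153%, 4.44%, 0.472% and 0.029% at 1000. Its 10 marker columns made up 12.3 CPM in code 1 of library 6562, with an exact Poisson interval of 11.62 to 13.02. Codes 2, 3 and 4 had 72.8 (71.8 to 73.8), 75.4 (72.2 to 78.6) and 39.8 (37.5 to 42.1) CPM.

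**Figure D3:**
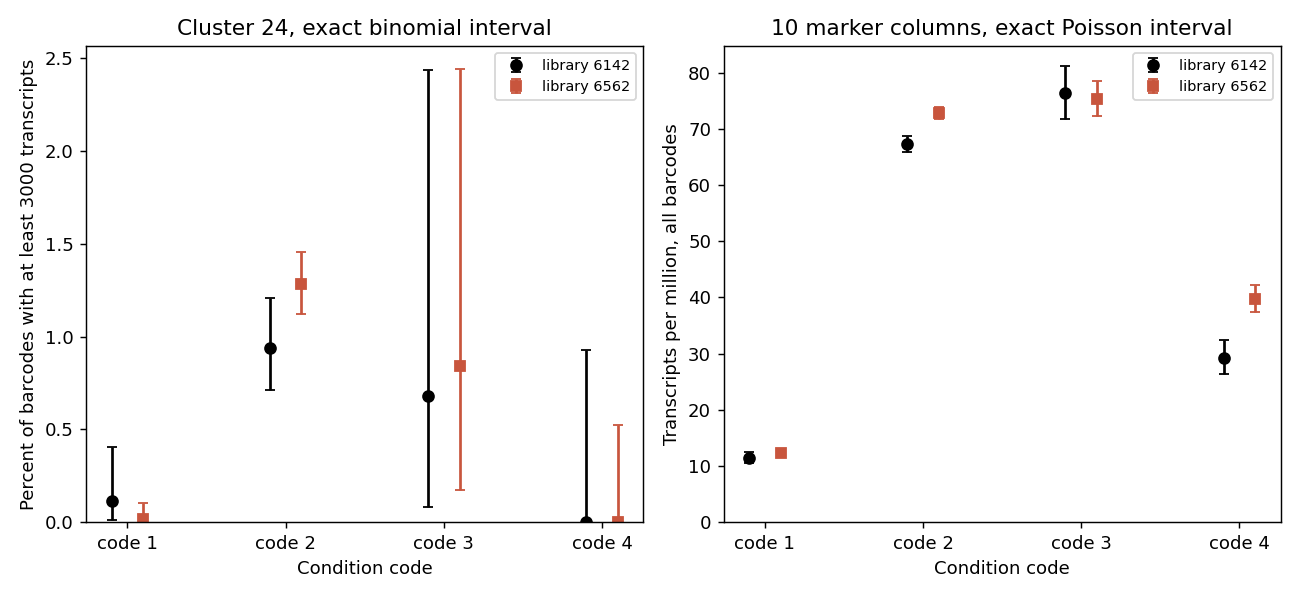
Left, cluster 24 as a percent of deep barcodes in each condition code, with exact binomial 95% intervals; right, CPM in its 10 marker columns over all barcodes, with exact Poisson 95% intervals. Circles stand for library 6142, in which the columns were chosen, and squares for library 6562, where they made up 12.3 CPM in code 1 and 72.8 in code 2.

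Summed over all barcodes, the profile of a code correlated between libraries with r of 0.990 to 0.998 across columns. Different codes of the same library correlated with r of 0.981 to 0.994. Columns are not independent replicates. The libraries shared 1291 deep barcodes where 1176.38 were expected by chance, and 100 of these fell in the same cluster where 79.4 were expected. With both libraries mixed from the same codes, they do not replicate a treatment.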

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

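The minimum of 3000 transcripts, the clusterings at 2000, 3000 and 5000, and the median of 1600 transcripts that defines a deep cluster were chosen after seeing the data. The minimum of 1000, resolution 0.5, the mean and each library alone were planned. Values are for codes 1 to 4 in order. Barcodes passing were 13551, 68988, 6133 and 4123 at 1000 transcripts, 7131, 24876, 650 and 1103 at 3000, and 6922, 36156, 3797 and 2195 in library 6142 alone. Library 6562 alone kept each of these counts within 1.5 times. The median of passing barcodes became 3527, 1769, 1517 and 1939 at 1000 transcripts, and 8935, 7933.5, 3925 and 4295 at 3000. It was 806, 758, 988 and 1024 in library 6142 and 724, 1150, 804 and 743 in library 6562. The mean in its place was 2401.54, 2718.52, 1154.15 and 1373.44. The percent of passing barcodes in deep clusters was 18.9, 23.1, 30.9 and 28.1 at resolution 0.5, and 62.8, 45.1, 83.0 and 83.8 at 1000 transcripts. It was 34.6, 23.8, 56.9 and 51.9 in library 6142 and 17.7, 25.1, 35.6 and 28.1 in library 6562. Code 1 lay below code 2 in both libraries together, in library 6562 and at resolution 0.5, and above it in library 6142 and at 1000 transcripts. A higher minimum removes background barcodes by its construction; the cause of the other changes was not tested. For the share of the cluster matched to cluster 24, 15 of 24 alternatives moved beyond the interval. From 1.23%, 6.22%, 2.77% and 1.46% at 500 transcripts it went to 0.153%, 4.44%, 0.472% and 0.029% at 1000, and to 0.042%, 1.19%, 0.77% and 0 at 3000. Code 3 had more passing barcodes than code 4 at 500 and 1000 transcripts and in each library alone, and fewer at 3000. Tests of genes, gene lists and shares per mouse, with their alternatives, were not run because no source used here ties codes to treatments or wells to mice. The alternative with doublets kept was not run, since none were removed. Shares of deep barcodes in codes 3 and 4 rest on 650 and 1103 barcodes.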

Other observations

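Tests of the transcript minimum, of code 1 or code 4 alone, of reads per transcript, of the number of deep barcodes, of the share reaching 5000 transcripts and of the wells with cluster 24 were chosen after the results were seen. Codes are not tied to treatments, so no biological explanation was tested for any pattern here.

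Codes 3 and 4 had few deep barcodes. Their reads per transcript were at least 0.996 of those in codes 1 and 2. Each library mixed all codes before sequencing, so its sequencing depth was common to all codes. That design argues against shallower sequencing of codes 3 and 4. The near-equality follows from the design and is no separate test. Fewer transcripts per nucleus may contribute: in cluster 6 of the passing barcodes the median was at most 0.400 of that in code 2, although higher background in code 2 can hide its shallow nuclei. Among deep barcodes, 23.8% (20.6% to 27.3%) of code 3 and 35.4% (32.5% to 38.3%) of code 4 reached 5000 transcripts, against 81.9% (80.9% to 82.7%) of code 1 and 76.8% (76.3% to 77.3%) of code 2. Fewer nuclei also stay open, with deep-cluster barcodes of codes 3 and 4 at most 0.251 of code 2. Code 1, outside the pattern, had 0.278 and 0.282. In library 6142 code 3 had 2160 against 2393 in code 1, and in library 6562 it had 4298 against 6763. Code 4 had 1139 and 2503, below code 1 in both libraries. Nuclei with too few transcripts drop out of these counts.

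Cluster 24 was nearly missing from codes 1 and 4. It was picked for the largest ratio of its share in code 2 to that in code 1, so the size of the pattern is partly selection. Absence from code 4 was not particular to it. Cluster 13 had 0 of 1103 deep barcodes in code 4 and 0 of 650 in code 3, against 2.82% in code 2. Cluster 22 had 0 of 1103 in code 4, against 1.56% in code 2. In code 1 the share of the matched cluster at 1000 transcripts was 0.0344 of that in code 2, with an upper limit of 0.0620. This cannot decide whether the minimum hides the cluster. Code 3 also had a low share there, 0.472% against 4.44% in code 2. Yet the marker columns of code 3 over all transcripts stood at 1.04 (0.990 to 1.08) of code 2 in library 6562. At 500 transcripts the shares of codes 1 and 2 lay nearer together, at 1.23% and 6.22%, in a matched cluster that also took in other barcodes. Whether code 1 held the cluster at the level of code 2, placed in other clusters, was asked of the marker columns. Over all transcripts of library 6562, with no minimum, these columns stood in code 1 at 0.169 (0.159 to 0.179) of code 2, under the bound of 0.5. That ratio cannot decide the question, since most marker RNA lay outside deep barcodes. In code 2 of that library, deep barcodes held 7102 of the 19058 marker transcripts. Cluster 24 was also formed and picked from both libraries together, so library 6562 was not held out. In deep barcodes of that library the marker columns of code 1 stood at 0.124 (0.109 to 0.140) of code 2, while cluster 24 held 0.019% of code 1 and 1.28% of code 2. The columns were thus lower in code 1, but placement elsewhere, or free RNA, stays open in it. A few odd wells of code 2 are argued against, since 12 of 12 wells held cluster 24 in both libraries. For codes 1 and 4 taken jointly the marker test was undecided, because code 4 stood at 0.546 (0.514 to 0.580), above the bound of 0.5 set before the result, and free RNA in the background was not separated from nuclei in that test. For code 4 alone the minimum cannot be told apart from absence, since 1 barcode at 1000 transcripts gave 0.0614 (0.0015 to 0.376) of the share in code 3.

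The match of cluster 24 across minimums has limits. At 500 transcripts 261 of the 305 barcodes fell in a cluster of 2372, with 1.23%, 6.22%, 2.77% and 1.46% of deep-cluster barcodes in codes 1 to 4. At 2000 transcripts 298 fell in a cluster of 656, with 6, 634, 16 and 0 barcodes. At 5000 transcripts 156 of them remained and formed no cluster of their own, with at most 35 in any cluster. In library 6142, where the marker columns were chosen, their level in code 4 was 0.435 (0.391 to 0.484) of that in code 2, and in code 3 it was 1.13 (1.06 to 1.21). The level of these columns was lower in deep barcodes than in barcodes under 500 transcripts in all 4 codes of library 6142 and in codes 1, 2 and 4 of library 6562, in values looked at after the results were seen. The fall was thus not particular to the codes with little of cluster 24. In code 2 of library 6562 they made up 84.0 CPM (75.7 to 92.9) under 500 transcripts and 41.5 CPM (40.5 to 42.5) in deep barcodes. In code 4 of that library the levels were 49.2 CPM (46.0 to 52.7) and 15.5 CPM (11.5 to 20.3). Those levels were 0.586 (0.519 to 0.663) and 0.372 (0.278 to 0.489) of code 2, and the latter was 0.285 (0.171 to 0.446) in library 6142. Code 1 of library 6562 had 19.9 CPM (17.99 to 22.04) and 5.14 CPM (4.55 to 5.79). Code 3 had 85.6 CPM (81.1 to 90.3) and 86.0 CPM (72.1 to 101.9), with no detectable difference, but in library 6142 it had 86.4 CPM (80.0 to 93.1) and 43.9 CPM (33.4 to 56.6). In deep barcodes code 3 stood at 2.07 (1.73 to 2.46) of code 2, and at 1.40 (1.06 to 1.82) in library 6142, while its share of cluster 24 in library 6562 was 0.84% (0.17% to 2.44%) against 1.28% (1.12% to 1.45%) in code 2.

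Wells of codes 1 and 2 deviated alike in both libraries, and codes 3 and 4 were not run. Over 2000 columns, the deviations of a well from its code correlated between libraries with a mean r of 0.46 in code 1 and 0.68 in code 2, against -0.04 and -0.06 for different wells. The permutation p was 1e-05 in both codes, the smallest that the permutations can give, and 10 and 12 of the 12 wells matched best with themselves. The amount of background is argued against as the whole cause, since without its linear trend r was 0.44 and 0.65 with a permutation p of 1e-05. Different material in the wells, such as different mice, may be a cause, but effects of the first-round reaction in a well are shared by both libraries as well and were not tested.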
